A study of Glycyrrhiza uralensis with 30 samples.

How the data were processed

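RNA was extracted from aboveground parts (stems and leaves) and underground parts (roots) of *Glycyrrhiza uralensis* seedlings and sequenced on an Illumina library protocol, per the labels' protocols. The 30 libraries fall into 10 groups of 3, by part of the plant and by time (0, 2, 6, 12 or 24 h) in a medium with 100 g/L of PEG 6000; groups were taken from the sample descriptions. The libraries carry numbers in their titles (1 to 3 at 2 h, 4 to 6 at 6 h, 7 to 9 at 12 h, 10 to 12 at 24 h, and 31 to 33 in control), and these numbers name the libraries here. The age is labelled as 60 days, whereas the protocol text speaks of 1 week of hydroponic growth; how these fit together is not stated in the labels.

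The authors deposited 1 table per library with TPM, a transcript abundance scaled within each library, for the same 34445 genes, to 2 decimals. TPM values are read numbers divided by transcript length and scaled to a fixed sum, so they hold shares of the RNA pool and no depth. The submitters' processing notes name fastp, HISAT2, StringTie, RSEM, DESeq2 and edgeR, without versions and without saying which of them made the TPM values. The genome build and the annotation are not given in the sources used here. The deposited TPM values of a library summed to between 928931 and 972586, so 2.74% to 7.11% of the nominal total of 1000000 lay outside the listed genes. Because each library is scaled to a fixed sum, a large rise in some genes lowers the TPM of all others; a second scaling was therefore tried. No 2 libraries held identical values. 4615 genes were at 0 in every library. A value of 0 is described as listed at 0. Without read numbers no counting interval or detection floor can be given, and low TPM values carry more counting error than high ones to an unknown extent. Near-identical gene copies can share reads, and how the authors assigned such reads is not stated, so single genes of such families are uncertain.

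From the deposited TPM, log2(TPM + 1) was computed and tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, Benjamini-Hochberg adjustment, threshold 0.05). Genes were kept with at least 1 TPM in at least 3 libraries of the fit. The comparisons of each time with the 0 h control, and the joint test over the 4 times, used the 15 libraries of a part in 1 fit, so that its 5 groups shared an estimate of the spread. The comparison of the parts at 0 h and the tests of a different response underground and aboveground used all 30 libraries. These designs, the rule for naming genes and most of the other settings tried were fixed before the data were examined. The rule named, in each part, 1 gene that rose and 1 that fell: called in the same direction at all 4 times, with no overlap between treated and control libraries, a mean of at least 10 TPM in the higher groups and the largest mean absolute log2 change. No aboveground gene met it, so the same conditions were applied to 2 h and 24 h alone, after the values were seen. The design had also fixed 18 gene lists (such as abscisic acid signalling, dehydrins and flavonoid synthesis) to be matched by gene name. They could not be applied, since the files do not pair identifiers with names and no annotation was used here.

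Groups of part-biased genes were set after the values were seen, as a difference of at least 3 on the log2(TPM + 1) scale between the means of the 15 aboveground and the 15 underground libraries. Fisher's exact test on the calls and camera were run on these groups, with the bias limit of 2 as well, but no enrichment is read from them, since 12 of the 15 libraries behind each mean were treated and a change under treatment helps to decide membership. Overlaps of calls between the parts were tested with Fisher's exact test. Overlaps between times were set beside 100 simulations of unchanged groups with the same spread and shared controls. Principal components were computed on the tested genes. Figures were drawn with matplotlib 3.10.9.

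The fits were tested on simulated data for the same genes and spread, with 200 genes changed. In the comparisons with control, 9% to 22% of genes changed 2-fold and 55% to 66% of genes changed 4-fold were recovered in the right direction, with 1 to 6 false calls. In the tests of a different response, 4% to 8% of 2-fold and 35% to 39% of 4-fold differences were recovered. So most 2-fold changes were missed at 3 libraries per group where 200 genes changed. The adjusted threshold is less strict where more genes change, and recovery in such comparisons was not simulated. The other settings fixed in advance were no filter, a stricter filter of at least 5 TPM, quantile normalization, limma without trend, a pseudocount of 0.1, only the 6 libraries compared, the library number as a block, and leaving out each library in turn. Median-ratio scaling, a quality weight per library and a bias limit of 2 on the log2 scale were added after the data were seen. Splicing was not analysed here.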

Results

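RNA levels were measured in seedlings of *Glycyrrhiza uralensis*, a licorice, during simulated drought. Polyethylene glycol 6000 (PEG 6000), a polymer that lowers the water potential of a solution and so makes water harder for roots to take up, was added at 100 g/L to the hydroponic medium. Aboveground parts (stems and leaves) and underground parts (roots) were sampled after 0, 2, 6, 12 and 24 h, with 3 libraries in each of the 10 groups and 30 libraries in all. The 0 h group of each part served as its control. The series was set up to follow how splicing responds to drought over time; splicing is not analysed here, and the values below are TPM, transcript abundances scaled to a fixed sum in each library, of 34445 genes. TPM keeps no read depth, so the depth of each library is unknown. The libraries had 18959 to 21776 genes at 1 TPM or more in the aboveground parts and 19906 to 20876 in the underground parts. The 10 most abundant genes held 6.17% to 11.7% of the summed TPM aboveground and 4.66% to 14.2% underground. The files do not pair gene identifiers with names, so 4 genes are given by identifier and the rest as groups. Nothing in the labels says whether the libraries of a group came from separate plants, so the p-values measure the spread between these samples, which may be technical. The labels list no controls at 2, 6, 12 or 24 h, and the control is labelled as distilled water where the treated groups had PEG in nutrient solution. Each comparison with control therefore covers the PEG, the medium and the time elapsed together.

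In the aboveground parts, the libraries of 2 h and 24 h lay apart from the others. On the first principal component, which held 31.1% of the variance, these 6 libraries scored from -116.2 to -51.5, and the 9 libraries of 0, 6 and 12 h scored from 16.6 to 89.3. In the underground parts the first component held 20.1% of the variance. The 2 h libraries scored from -88.3 to -65.3 there, those of 24 h from -36.6 to -7.79, those of 12 h from -12.1 to 19.1, those of 6 h from 18.2 to 51.2 and the controls from 43.4 to 74.5.

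**Figure D1:**
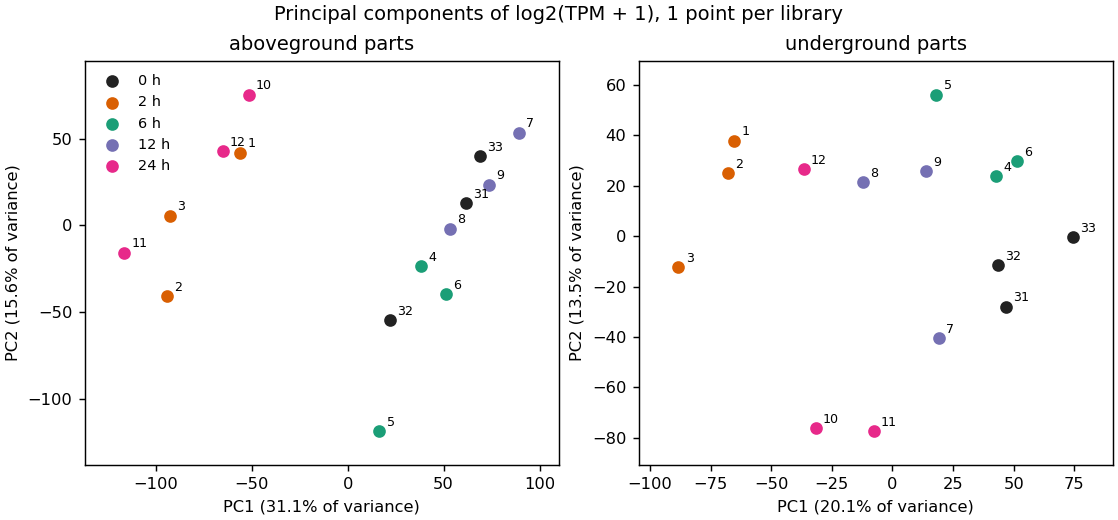
First and second principal components of log2(TPM + 1) for the 15 libraries of each part of the plant, with 1 point per library, coloured by time under PEG 6000 and marked with its library number. In the aboveground parts the 2 h and 24 h libraries score from -116.2 to -51.5, and the other libraries score from 16.6 to 89.3.

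The aboveground comparisons ask which genes of stems and leaves differed from control after each time. At 2 h, 1167 genes were higher and 1290 lower than control, among 23541 tested with limma at a Benjamini-Hochberg adjusted p under 0.05. Of these, 963 rose and 1052 fell at least 2-fold. At 24 h, 1390 genes rose and 2115 fell, 1124 and 1611 of them at least 2-fold. Few genes differed in between. At 12 h, 55 genes rose and 149 fell. At 6 h limma called 0 genes, with or without a mean-variance trend, although 1540 genes had an unadjusted p under 0.05, against 1177 by chance, and the smallest adjusted p was 0.3024. In simulated data for the 6 h comparison, 9% of genes changed 2-fold and 57% of genes changed 4-fold were recovered, so 100 genes changed 4-fold would have given calls, while most 2-fold changes were missed. The test of any difference from control over the 4 times called 5212 genes.

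Glyur000063s00005870 was the gene with the largest mean rise over 2 h and 24 h among the 660 that rose at both times with no overlap between the libraries, a condition that chance meets in either direction for 10% of genes at each time. It went from 1.85 ± 0.98 TPM in control to 2519 ± 1033 TPM at 2 h (SD, n = 3). It stood at 8.45 ± 1.504 TPM at 6 h, 1.96 ± 1.19 TPM at 12 h and 284.9 ± 120.3 TPM at 24 h (SD, n = 3). On the log2(TPM + 1) scale, which understates changes of low genes, it rose by 9.75 (SE 0.41, limma adjusted p = 2.73e-08) at 2 h and by 6.64 (SE 0.41, adjusted p = 6.90e-07) at 24 h. Its log2 differences of 1.78 at 6 h (adjusted p = 0.413) and 0.04 at 12 h (adjusted p = 0.9995) did not pass the test. Glyur000742s00025064 had the largest mean fall among 691 such genes. It was at 4153 ± 3246 TPM in control, 16.2 ± 15.6 TPM at 2 h and 0.607 ± 0.297 TPM at 24 h (SD, n = 3). Its log2 changes were -8.06 (SE 0.72, adjusted p = 1.69e-05) at 2 h and -11.09 (SE 0.72, adjusted p = 9.48e-07) at 24 h. At 6 h it was at 6948 ± 3810 TPM and at 12 h at 2320 ± 1551 TPM (SD, n = 3), and neither passed the test against control (limma adjusted p = 0.785 and 0.860). Both genes were chosen after their values were seen, because no aboveground gene was called in one direction at all 4 times.

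The median gene was not at 0 in these comparisons. The median log2 difference of all tested genes was -0.15 at 2 h, 0.10 at 12 h and -0.18 at 24 h aboveground, and -0.12 at 2 h underground, and it became -0.029, -0.0032 and -0.014 aboveground and -0.0098 underground when the values were rescaled by median ratios. Rescaling turned the balance of the calls: aboveground, 1519 genes rose and 1018 fell at 2 h and 1946 rose and 1770 fell at 24 h, so that the share of calls that rose went from 47.5% to 59.9% and from 39.7% to 52.4%. Underground at 2 h, 1928 rose and 1434 fell after rescaling, 57.3% against 42.8% as deposited. Leaving out single libraries moved the aboveground counts too. It also leaves fewer libraries in a group, so a lower count alone does not single out that library. The 2 h count of 2457 became 1279 without control library 31 and 1362 without library 3 of 2 h, and the 1290 falls among them became 812 without control library 33. The 24 h count of 3505 became 2224 without control library 31, and its 2115 falls became 1270 without library 11 of 24 h. The count of falls of at least 2-fold was 538 at 2 h without control library 31, 545 without library 3 of 2 h, and 1007 at 24 h without library 11. The 12 h count of 204 became 117, 116 or 121 without library 7, 8 or 9 of 12 h, and 132 or 127 without control library 31 or 32; its 55 rises became 30 without control library 33. At 6 h, 1 gene was called without control library 31, 1 without control library 32 and 5 without control library 33.

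**Figure D2:**
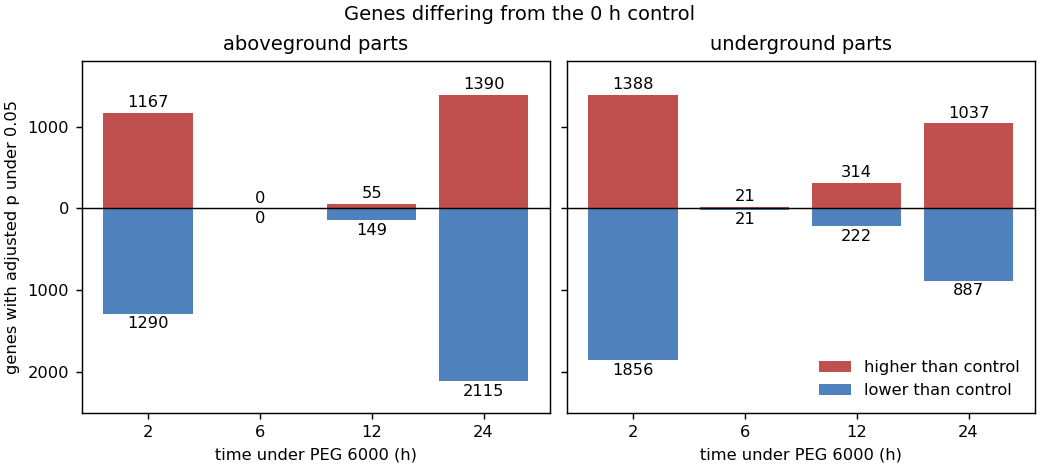
Number of genes with a limma adjusted p under 0.05 that were higher (red, up) or lower (blue, down) than the 0 h control, by hours under PEG 6000, in aboveground and underground parts. Aboveground the counts fell from 1167 and 1290 at 2 h to 0 at 6 h and stood at 1390 and 2115 at 24 h; underground they were 1388 and 1856 at 2 h, 21 and 21 at 6 h and 1037 and 887 at 24 h.

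In the underground parts, 1388 genes rose and 1856 fell at 2 h among 23107 tested with limma, 959 and 1188 of them at least 2-fold. At 6 h, 21 rose and 21 fell, all at least 2-fold. At 12 h, 314 rose and 222 fell, and at 24 h 1037 rose and 887 fell. The test over the 4 times called 3017 genes. Here some genes kept their direction throughout: 13 rose and 7 fell at all 4 times, with 0 on average in 100 simulations of unchanged groups with the same controls. Such simulations give chance with no effect at any time, and leave open how many genes shared controls add where genes do change.

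Glyur002055s00039240 had the largest mean rise of the 13 genes, chosen by a rule fixed before the data were examined. Its level in roots was 13.97 ± 11.36 TPM in control, 280.1 ± 206.5 TPM at 2 h, 225 ± 106 TPM at 6 h, 638 ± 174 TPM at 12 h and 434 ± 209 TPM at 24 h (SD, n = 3). The log2 changes were 4.31, 4.10, 5.70 and 5.07 (SE 0.63 each), with limma adjusted p = 9.05e-04, 0.0216, 7.53e-04 and 5.55e-04. The call at 6 h was lost without library 4 or 5 of 6 h (adjusted p = 0.123 and 0.127), without control library 31 or 33 (0.0917 and 0.0568), and with only the 6 libraries compared (0.102); over all alternatives its adjusted p ranged from 0.0141 to 0.127. In the aboveground parts the same gene was at 0.230 ± 0.293 TPM in control and 9.33 ± 8.08 TPM at 24 h (SD, n = 3), with a limma adjusted p of 0.0929. The gene named by the rule among those that fell was Glyur000012s00000609. It had 7.82, 22.5 and 6.31 TPM in the 3 underground controls and was listed at 0 in all 12 treated underground libraries and in all 15 aboveground libraries, so no fold is given.

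**Figure D3:**
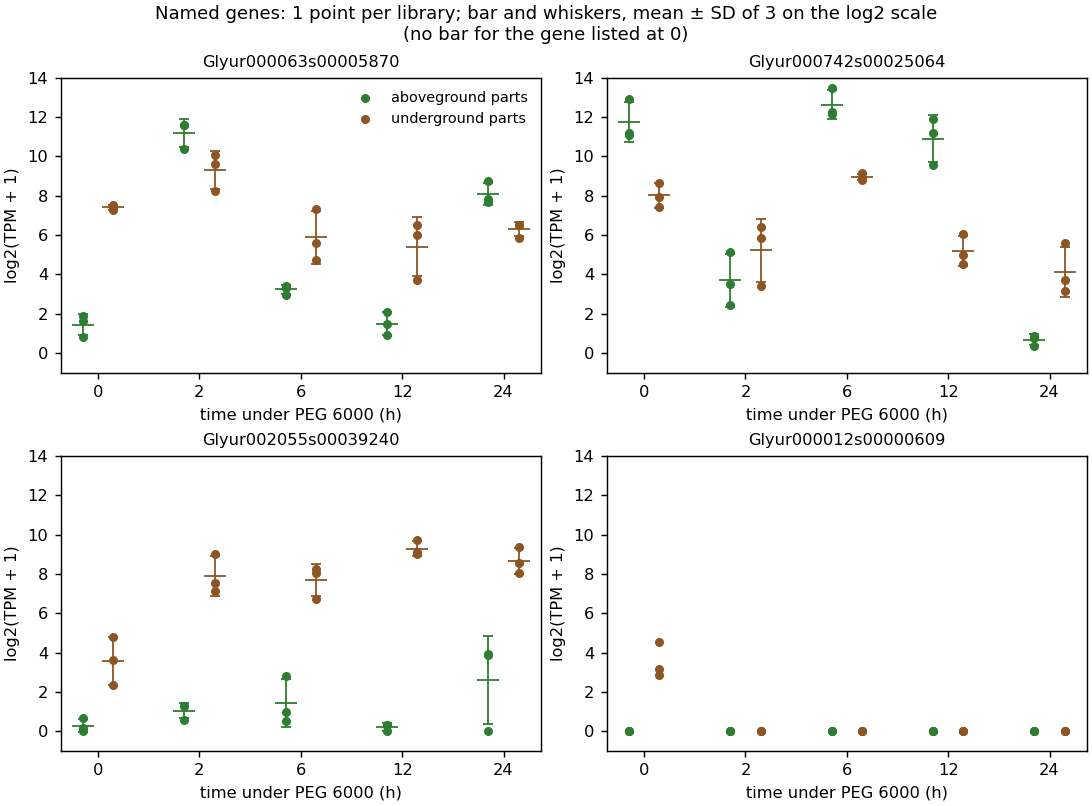
Level of the 4 named genes as log2(TPM + 1) in aboveground (green) and underground (brown) parts by hours under PEG 6000; points are libraries, and bars with whiskers are the mean ± SD of 3 libraries on the log2 scale, left out for the gene listed at 0. Glyur000063s00005870 and Glyur000742s00025064 moved far from control aboveground at 2 h and 24 h, and Glyur002055s00039240 was above control underground at all 4 times.

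Several underground counts fell when a single library was left out, which also leaves fewer libraries in a group. At 2 h, 1998 genes were called without library 3 of 2 h, in place of 3244, with 714 in place of 1188 falls of at least 2-fold, and the count of falls went from 1856 to 1137 without control library 32. At 6 h the 42 calls became 12 or 16 without library 4 or 5 of 6 h, and 15 or 27 without control library 31 or 32, and its 21 falls became 9 without library 6. At 12 h the 536 calls became 309, 187 or 209 without library 7, 8 or 9 of 12 h, and 226 or 309 without control library 31 or 33, and its 222 falls became 147 without control library 32. At 24 h the 1924 calls became 1167 without library 10 of 24 h, and 1028 or 1250 without control library 31 or 32. The 20 genes called in one direction at all 4 times became 3 or 5 without library 4 or 5 of 6 h, and 4, 13 or 10 without control library 31, 32 or 33.

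The comparison of the parts at 0 h asks how shoots and roots differed before treatment. Of 25420 genes tested with limma over all 30 libraries, 4291 were higher aboveground and 5003 higher underground, 3649 and 3482 of them at least 2-fold. Groups of genes biased to a part were then set from the data: 1060 genes averaged at least 8-fold higher in the 15 aboveground libraries on the log2(TPM + 1) scale, and 573 at least 8-fold higher in the 15 underground libraries. These groups were chosen on the same libraries, after the values were seen, so their direction is not independent evidence.

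Genes biased to the aboveground parts went both ways there. Of the 1060, 121 rose and 183 fell at 2 h (11.4% and 17.3%, with 4.65% and 4.92% of other genes), 7 rose and 72 fell at 12 h (0.66% and 6.79%, with 0.214% and 0.343%), and 163 rose and 146 fell at 24 h (15.4% and 13.8%, with 5.46% and 8.76%). No enrichment is read from these shares, because the treated libraries helped to set the groups. With a bias limit of 2 on the log2 scale the group held 1946 genes, of which 203 rose and 321 fell at 2 h, 13 rose and 94 fell at 12 h, and 279 rose and 301 fell at 24 h. After median-ratio rescaling, 112 of the 1060 fell at 2 h, 1 rose at 12 h and 96 fell at 24 h; with library weights 17 rose at 12 h; and with only the 6 libraries compared 0 rose and 18 fell at 12 h and 97 fell at 24 h. At 2 h, 77 rose and 111 fell without library 3 of 2 h, and 76 rose and 101 fell without control library 31. At 12 h, 43 fell without library 7 of 12 h or control library 32; 2, 2 or 3 rose without library 7, 8 or 9 of 12 h, and 2, 4 or 2 without control library 31, 32 or 33.

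Genes biased to the underground parts more often rose than fell there. Of the 573, 99 rose and 53 fell at 2 h (17.3% and 9.25%, with 5.72% and 8.00% of other genes), 44 rose and 4 fell at 12 h (7.68% and 0.698%, with 1.20% and 0.967%), and 86 rose and 21 fell at 24 h (15.01% and 3.67%, with 4.22% and 3.84%). A rise under treatment itself helps a gene into this group, so no enrichment is read here either. With a bias limit of 2 the group held 1422 genes, of which 194 rose and 150 fell at 2 h, 82 rose and 11 fell at 12 h, and 159 rose and 66 fell at 24 h. With library weights 89 of the 573 fell at 2 h, and 82 rose and 22 fell at 12 h; with only the 6 libraries compared 27 fell at 2 h, 1 fell at 12 h, and 44 rose and 5 fell at 24 h. At 2 h, 35 or 27 fell without library 1 or 3 of 2 h, and 34 or 35 without control library 32 or 33. At 12 h, 28 rose and 1 fell without library 8 of 12 h, 29 rose without library 9 of 12 h, and 2 fell without control library 31 or 33.

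The level of genes biased to the other part varied between libraries. Among underground libraries, the median log2(TPM + 1) of aboveground-biased genes was 1.77 in library 3 of 2 h and 1.60 in library 6 of 6 h, and 0.79 to 1.25 in the rest. Among aboveground libraries, that of underground-biased genes was 0.81, 0.96 and 1.68 in the controls. It was 1.80, 1.10 and 2.11 in libraries 1, 2 and 3 of 2 h, and 1.89, 0.44 and 1.90 in libraries 10, 11 and 12 of 24 h. It was 2.08, 1.13 and 1.04 in libraries 4, 5 and 6 of 6 h, and 1.57, 1.21 and 1.82 in libraries 7, 8 and 9 of 12 h.

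Many genes were called in the same direction in both parts. Among 21662 genes tested in both, 251 rose and 242 fell in both at 2 h, where independent lists would share 66.6 and 98.7 (one-sided Fisher's exact test, adjusted p = 2.24e-80 and 4.96e-41 over 8 tests, across genes, which are not independent replicates). At 24 h, 210 rose and 321 fell in both, against 57.45 and 80.98 (adjusted p = 4.49e-64 and 2.76e-114). At 12 h, 6 rose and 24 fell in both, against 0.59 and 1.25 (adjusted p = 3.37e-05 and 6.49e-24). At 6 h there was no aboveground call to share. These tests treat the parts as independent, so noise shared by libraries of the 2 parts would add to the overlap, and a shared response is not shown by it. Opposite calls also occurred, but each count was below what independent lists of these sizes would give. At 2 h, 46 genes rose aboveground and fell underground, and 21 did the reverse. At 24 h there were 14 and 15. The 14 became 28 with quantile normalization, 26 with median-ratio rescaling and 27 with library weights, and the 15 became 9 with limma without trend. With library weights the 46 and 21 became 110 and 69, 474 genes fell in both at 2 h, and 22 rose and 44 fell in both at 12 h; without a filter 3 rose in both at 12 h. The shared counts of 493, 30 and 531 genes at 2, 12 and 24 h became 321 without aboveground library 3 of 2 h, 19 or 18 without library 8 of 12 h from aboveground or underground, and 309 without underground control library 31. The 242 genes that fell in both at 2 h became 131 or 159 without library 3 of 2 h from aboveground or underground, and 147 without aboveground control library 31. At 24 h, 114 rose in both without underground control library 31, and 212, 195 or 207 fell in both without underground library 10 of 24 h or underground control library 31 or 32. At 12 h, 2 or 1 rose in both without aboveground library 8 or 9 of 12 h, 3 without any single aboveground control library, underground library 8 of 12 h or underground control library 31, and 15 fell in both without underground library 8. The opposite calls of 46 and 21 genes at 2 h became 30 and 9 without aboveground library 3, 24 and 8 without aboveground control library 31, 27 and 11 without underground library 2, and 24 and 13 without underground library 3; the first count was 25 without underground control library 32, and the second 13 without aboveground control library 33. Those of 14 and 15 genes at 24 h became 9 and 6 without aboveground library 11, 7 and 7 without aboveground control library 31, and 9 and 7 without underground control library 31; the 14 became 9 or 8 without underground library 10 or underground control library 32, and the 15 became 8 without control library 33 of either part.

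Whether the response differed between the parts was tested directly, as the log2 change underground minus the log2 change aboveground. The difference passed limma's test for 1950 genes at 2 h, 1 at 6 h, 200 at 12 h and 1528 at 24 h among 25420, and for 3141 genes over the 4 times together. The single gene at 6 h was Glyur000012s00000609, which was listed at 0 in every aboveground library. It could not fall there, so no difference of response is read from it. Of the 1950 genes at 2 h, 654 were called in the aboveground comparison only, 711 in the underground comparison only, 67 in opposite directions, 69 in the same direction and 254 in neither comparison, and 195 were tested in 1 part only. Of the 1528 at 24 h, 842 were called aboveground only, 285 underground only, 29 in opposite directions, 83 in the same direction and 141 in neither, and 148 were tested in 1 part only. Glyur000063s00005870 and Glyur000742s00025064 were chosen for their aboveground changes, so larger changes aboveground than underground are expected of them from the choice. Glyur000063s00005870 differed between the parts by -7.85 at 2 h (SE 0.88, limma adjusted p = 1.11e-05) and by -7.75 at 24 h (SE 0.88, adjusted p = 9.60e-06). Its underground levels were 168.8 ± 12.7 TPM in control, 721 ± 393 TPM at 2 h and 78.6 ± 18.2 TPM at 24 h (SD, n = 3). Neither change passed limma's test (adjusted p = 0.102 and 0.406). At 2 h all 3 underground libraries (788, 299 and 1076 TPM) lay above the underground controls (155 to 180 TPM), so a rise there is not excluded. Glyur000742s00025064 fell in both parts at 2 h and 24 h; its underground changes of -2.79 (SE 0.74, adjusted p = 0.0248) and -3.87 (SE 0.74, adjusted p = 0.00688) differed from the aboveground ones by 5.27 (SE 1.09, adjusted p = 0.00386) and 7.21 (SE 1.09, adjusted p = 2.99e-04). The counts changed when single libraries were left out, which also leaves fewer libraries in a group. At 2 h 1204 genes were called without aboveground control library 31. At 24 h 1000 were called without that library and 918 without aboveground library 11 of 24 h, which had the fewest genes at 1 TPM or more (18959). At 12 h the count was 130 or 118 without underground library 8 or 9 of 12 h, and 124 or 106 without underground control library 31 or 33. At 6 h it was 8 without aboveground library 5 of 6 h, 3 without aboveground control library 31, and 0 without underground control library 31 or 32.

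The times of a part were also compared with each other, in comparisons added after the data were seen. Aboveground, the 2 h and 24 h groups differed in 472 genes, whereas 2901 genes differed between 2 h and 6 h, 4189 between 2 h and 12 h, 4126 between 6 h and 24 h and 4280 between 12 h and 24 h. The 6 h and 12 h groups differed in 385. Underground, 162 genes differed between 12 h and 24 h and 42 between 6 h and 12 h, against 1054 between 2 h and 24 h and 1844 between 2 h and 6 h. With library weights the underground 162 became 276, the 42 became 339 and the 1844 became 3598, and the aboveground 385 became 1101. Leaving out single libraries, which also leaves fewer libraries in a group, moved many of these counts. Aboveground, the 472 genes became 230 or 182 without library 1 or 2 of 2 h, and 308 or 216 without library 10 or 11 of 24 h; the 2901 became 1899 without library 3 of 2 h, and 1815 or 1820 without library 5 or 6 of 6 h; the 4189 became 2723 without library 3 of 2 h; and the 385 became 157, 163 or 210 without library 4, 5 or 6 of 6 h, and 137, 198 or 254 without library 7, 8 or 9 of 12 h. Underground, the 162 genes became 67, 86 or 86 without library 7, 8 or 9 of 12 h, and 82 or 300 without library 10 or 12 of 24 h; the 42 became 20, 24 or 21 without library 4, 5 or 6 of 6 h, and 19 without library 8 of 12 h; the 1054 became 473 or 362 without library 1 or 3 of 2 h, and 407, 390 or 1592 without library 10, 11 or 12 of 24 h; and the 1844 became 953 without library 3 of 2 h, and 1003 or 765 without library 4 or 6 of 6 h.

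**Figure D4:**
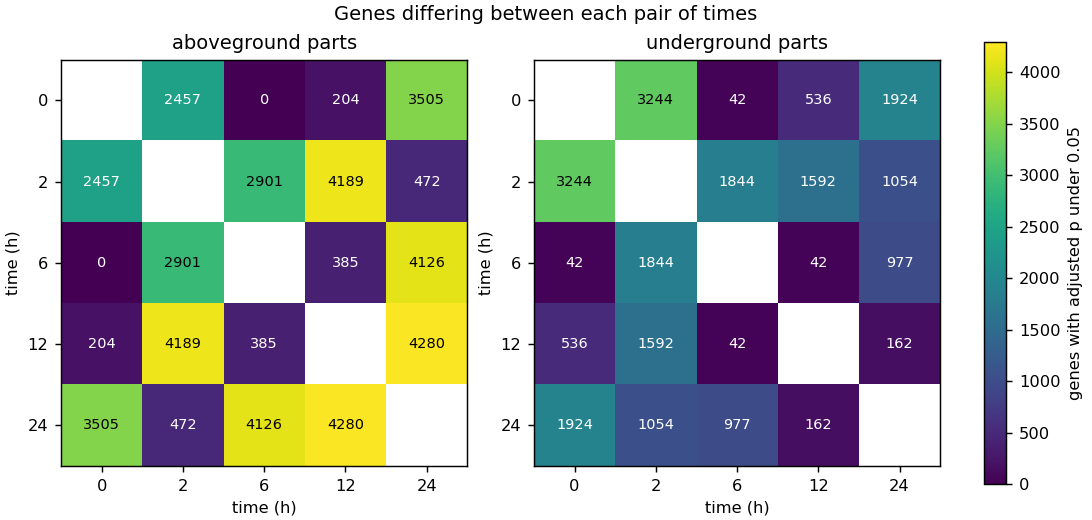
Number of genes with a limma adjusted p under 0.05 between each pair of times, in hours, for aboveground and underground parts; colour gives the same count as the printed number. Aboveground, 2 h and 24 h differ in 472 genes, and each differs from 0, 6 and 12 h in 2457 to 4280 genes.

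Genes called at 2 h were often called in the same direction at 24 h. Aboveground, 714 genes rose and 867 fell at both times, where independent lists would share 68.9 and 115.9 and at most 1 gene was shared in any of 100 simulations of unchanged groups against the same controls, whose lists hold few calls to share. Underground, 499 rose and 573 fell at both, against 62.3 and 71.3 for independent lists. The later underground times overlapped as well: 261 of the 314 genes that rose at 12 h also rose at 24 h, and 147 of the 222 that fell at 12 h also fell at 24 h, against 14.1 and 8.52. With library weights 480 rose and 428 fell at both 12 h and 24 h underground, and 906 fell at both 2 h and 24 h. Aboveground, 435 rose and 428 fell at 2 h and 24 h without control library 31, and 455 fell without library 3 of 2 h. Underground, 280 rose at both without control library 31, and 378, 333 or 351 fell without library 10 of 24 h or control library 31 or 32. Of the genes shared by underground 12 h and 24 h, 148, 106 or 110 rose and 91, 50 or 57 fell without library 7, 8 or 9 of 12 h, 109 rose and 58 fell without control library 31, 90 fell without control library 32 and 140 rose without control library 33. The log2 changes at 2 h and 24 h aboveground correlated across genes at r = 0.748, against 0.5 in the simulated unchanged groups, and their covariance of 0.701 exceeded the simulated 0.137 by 0.564. Underground the covariance of the same times was 0.445, against 0.116. For 2 h and 12 h aboveground the covariance was 0.0458, below the simulated 0.137. The 4 comparisons of a part share 3 control libraries, too few to split, so part of the excess overlap may come from the shared controls.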

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

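The tests that weigh explanations below, and the statement of what other splits of the libraries would show, were written after the results were seen; the draw of splits for the differences between the parts was also changed once after a first result, with no change in reading. The tests of a difference were planned, but the named genes were chosen for their change in 1 part, so their own differences are not independent evidence. The response underground differed from that aboveground, by a test of the difference, in 1950 genes at 2 h, 1 at 6 h, 200 at 12 h and 1528 at 24 h. Among the named genes, Glyur000063s00005870 differed by -7.85 at 2 h and -7.75 at 24 h, Glyur000742s00025064 by 5.27 at 2 h and 7.21 at 24 h, and Glyur002055s00039240 by 5.76 at 12 h (SE 1.12, limma adjusted p = 0.0101), as log2 change underground minus aboveground. With library weights the difference of Glyur000063s00005870 at 6 h passed too (-3.89, limma adjusted p = 0.0281, against 0.3375 without weights). Glyur000012s00000609 passed at all 4 times (limma adjusted p = 5.60e-06, 6.16e-05, 2.05e-05 and 4.51e-06) and was the 1 gene at 6 h. It is listed at 0 in every aboveground library and every treated underground one, so no fold is given. It could not fall aboveground, so the test only repeats its underground change. Its own spread comes from the 3 underground controls alone, so no difference of response is read from these p-values. The difference of Glyur002055s00039240 at 12 h did not pass with a pseudocount of 0.1 (adjusted p = 0.202); its adjusted p ranged from 0.00537 to 0.202 over all alternatives and left-out libraries. At 2 h its difference of 3.54 did not pass (adjusted p = 0.0536), but passed with the stricter filter (0.0472) and without underground control library 32 (4.13, adjusted p = 0.0337).

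Other splits of the same libraries into groups of the same sizes were drawn for these counts, 100 in each case with the real one included. At 2 h, 2 of the 100 splits gave a count as large as the real 1950, with 4931 as the highest other. At 12 h only the real split reached 200, with 164 as the highest other, and over all times only the real split reached 3141, with 190 as the highest other. For both, chance without a response in either part can be excluded only if the libraries of a group are independent samples. The labels do not state this. Such an exclusion would also not settle whether the responses differ. At 24 h, 8 of 100 splits gave at least 1528, with 5214 as the highest other. The other splits that reached the real count at 2 h and 24 h, 1 and 7 of them, all kept the real groups of at least 1 part. In such splits treated and control could also be exchanged. They still hold the real response of that part, so the shares at 2 h and 24 h give no verdict on chance. The splits that broke the groups of both parts gave at most 9 genes at 2 h, 153 at 6 h, 23 at 12 h and 16 at 24 h. All splits exchanged libraries within a part, so at best they stand for no response in either part. Whether equal responses of the parts would give such counts was not tested. At 6 h, 39 of 100 splits gave at least the 1 gene found, so chance cannot be excluded; the highest other was 153.

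The time courses were split in the same way. Only 1 of 100 splits, the real one, reached 5212 genes aboveground, with 371 as the highest other. Only 1 of 100 reached 3017 underground, with 224 as the highest other. Chance can be excluded for both only if the libraries of a group are independent samples, which the labels do not state. Differences between plants or pools shared by a group are not excluded. A comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. For aboveground 2, 6, 12 and 24 h the real counts were 2457, 0, 204 and 3505 and the highest of the other splits 2, 13, 5 and 5. For underground the real counts were 3244, 42, 536 and 1924 and the highest others 3, 5, 4 and 3. For the parts at 0 h they were 9294 and 7. The real count was reached by 1 split of 10 in each of these, except for aboveground 6 h, where a count of 0 was reached by all 10.

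In the aboveground parts the 2 h and 24 h libraries stood apart from those of 0, 6 and 12 h. A lower number of genes at 1 TPM or more was not common to the 2 h and 24 h libraries. It was 21269 and 21250 in libraries 10 and 12 of 24 h and 18959 to 20813 in the rest, against 20587 to 21486 in the controls. With that number as a covariate, 89.7% of the calls at 2 h and 24 h kept their direction and stayed past the threshold. So a lower number does not account for the pattern as a whole. The covariate follows the pattern only in part, so the share kept says little by itself. Root tissue in the 2 h and 24 h libraries can raise a gene no higher than its level in roots. It does not account for all of the rises, since 62.56% of the genes that rose had a lowest treated level above the highest underground level of the same time. Genes that fell were not covered by this test, so root tissue is not excluded for them. The median level of underground-biased genes was above every control (0.81 to 1.68) in libraries 1 and 3 of 2 h and 10 and 12 of 24 h (1.80, 2.11, 1.89 and 1.90). The same held for library 4 of 6 h and library 9 of 12 h (2.08 and 1.82), but not for library 2 of 2 h or 11 of 24 h (1.10 and 0.44). A daily rhythm that began with the controls on a common schedule would bring 24 h back to the state of 0 h, yet 3505 genes differed between those times, more than at 2 h. A rhythm with controls collected at another clock time may account for the closeness of 24 h and 2 h (472 genes between them), and a treatment response that depends on its length may do so too (2901 genes between 2 h and 6 h). These cannot be told apart, because harvest clock times are not in the labels and no untreated plants of 2 to 24 h were used here.

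In the underground parts the count at 2 h exceeded those at the later times. Stem or leaf tissue in the 2 h root libraries does not account for all of the rises, since 60.73% of the genes that rose had a lowest treated level above the highest aboveground level of 2 h. Genes that fell were not covered by this test, so such tissue is not excluded for them. Library 3 of 2 h had a raised median level of aboveground-biased genes (1.77, against 0.79 to 1.25 in other underground libraries but library 6 of 6 h). Library 3 alone does not account for the higher count at 2 h: 1998 genes were called at 2 h without it, and 1167, 1501 or 1587 at 24 h without library 10, 11 or 12 of 24 h. The change of solution at the start of treatment and an early response to PEG both stay open as untested explanations.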

How the results depend on the processing

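Median-ratio scaling, library weights and the lower bias limit were chosen after seeing the data; all other alternatives were planned. No named gene turned its direction in a call. The majority of calls turned from falls to rises with median-ratio scaling aboveground at 2 h and 24 h and underground at 2 h (59.9%, 52.4% and 57.3% rose), and with quantile normalization at 2 h in both parts (53.9% and 50.3%), and from rises to falls with the latter underground at 24 h (48.7% rose). It also turned at 2 h in both parts with only the 6 libraries compared, underground at 24 h with library weights, and at 2 h without library 3 of 2 h of either part or aboveground control library 31 or 33, so no majority is read from the calls of 2 h and 24 h. The counts that answer a comparison stayed within 1.5 times their value with no filter, the stricter filter, quantile normalization, limma without trend and median-ratio scaling. With a pseudocount of 0.1 the difference between the parts at 12 h fell to 122 genes, the only such count that moved by over 1.5 times there; the cause was not tested. Library weights gave higher counts: 3900, 17 and 356 aboveground at 2, 6 and 12 h; 756 and 1594 underground at 6 and 12 h, 5835 over its time course and 162 at all 4 times; 3661, 108 and 379 for the difference between the parts at 2, 6 and 12 h; and 847, 2 and 66 shared by both parts at 2, 6 and 12 h; the cause was not tested. With only the 6 libraries compared, which leaves fewer samples to estimate the spread, 1443, 5, 41 and 1610 genes were called aboveground and 1524, 18, 348 and 545 underground at 2, 6, 12 and 24 h. Leaving out each library in turn leaves fewer libraries in a group, so a lower count alone does not single out a library. Underground, even the highest count so found at 2, 6, 12 and 24 h lay below the count with every library. The ranges were as follows. Aboveground they were 1279 to 2508 at 2 h, 0 to 5 at 6 h, 116 to 136 at 12 h, 2224 to 3361 at 24 h, and 0 to 1 at all 4 times. Underground they were 1998 to 2683, 12 to 37, 187 to 397 and 1028 to 1587, and 3 to 26 at all 4 times. For the difference between the parts they were 1204 to 2199, 0 to 8, 106 to 173 and 918 to 1895 at 2, 6, 12 and 24 h, and for genes shared by both parts 321 to 475, 18 to 26 and 309 to 518 at 2, 12 and 24 h. The time courses (4406 to 5382 aboveground, 2184 to 3704 underground), the joint difference (2664 to 3365) and the parts at 0 h (7862 to 8923) stayed within 1.5 times. Of 1350 other values under the alternatives, 1144 kept, 201 moved (137 higher, 64 lower), 2 lost and 3 gained a call; of 1440 with a library left out, 1030 kept, 405 moved (39 higher, 366 lower), 4 lost their call, all of them Glyur002055s00039240 at 6 h, and 1 gained one. Aboveground and underground libraries of a time share title numbers whose meaning is not in the labels. Same-numbered libraries deviated together from their group means in 14 of 15 pairs at r over 0.1 (0.097 to 0.345), and 14 of 15 aboveground libraries correlated best with their own number over all times and 15 of 15 within their time, so the numbers hint at a pairing, although r is not over 0.1 in every pair, which was required to pair them. Deviations shared by number would also correlate the changes of the 2 parts (r = 0.257 at 6 h and 0.303 at 2 h). With the number as a block, 9983 genes differed between the parts at 0 h (8992 of them called the same way without it), and 2261, 1, 222 and 1694 differed in response at 2, 6, 12 and 24 h; the difference of Glyur002055s00039240 at 2 h passed with it (3.54, limma adjusted p = 0.0275, against 0.0536), and no other tested difference of Glyur000063s00005870, Glyur000742s00025064 or Glyur002055s00039240 changed its call. No paired analysis was possible because treated and control libraries share no number, for the comparisons within a part. The planned set test on named gene lists was not run, since the identifiers have no names here. Depth is unknown in TPM, so how far it limits low genes cannot be stated.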

Other observations

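All tests in this part were chosen after the results were seen. Aboveground, some genes that fell at 12 h were genes that rose at 2 h or 24 h, and others fell at those times too. Of the 149 genes lower than control at 12 h, 54 were higher at 2 h and 47 were higher at 24 h, where independent lists would give 7.39 and 8.80. Of the same 149 genes, 16 were also lower at 2 h and 35 also lower at 24 h, against 8.16 and 13.4. Opposite calls were fewer among risers: of the 55 genes that rose at 12 h, 5 fell at 2 h and 4 fell at 24 h, against 3.01 and 4.94. These 5 and 4 became 10 and 8 with quantile normalization and 21 and 13 with library weights, and the 5 became 3 with a pseudocount of 0.1. Between 2 h and 24 h themselves opposite calls were few, 4 genes that rose at 2 h and fell at 24 h and 0 the other way, against 104.9 and 76.2. Underground, 11 genes rose at 2 h and fell at 12 h, against 13.3, and 2 did the reverse, against 25.2. Of the 21 underground genes that fell at 6 h, 4 rose at 2 h, against 1.26. That count became 2 with median-ratio rescaling or without library 4 or 5 of 6 h, 7 without library 2 of 2 h, and 14 with library weights. These counts set lists against the same 3 controls. They changed when single libraries were left out, which also leaves fewer libraries in a group. The 54 genes became 32 or 33 without library 7 or 8 of 12 h, and 30, 35 or 28 without control library 31, 32 or 33; the 47 became 28 or 31 without library 7 or 8 of 12 h, and 27 without control library 33. The 5 became 2 or 3 without library 2 or 3 of 2 h, 1 or 2 without library 8 or 9 of 12 h, and 0 without control library 31 or 33; the 4 that rose at 12 h and fell at 24 h became 2 or 1 without library 8 or 9 of 12 h, and 1, 2 or 1 without control library 31, 32 or 33. The 4 that rose at 2 h and fell at 24 h became 2, 1 or 7 without library 10, 11 or 12 of 24 h, and 1, 2 or 0 without control library 31, 32 or 33, and the 0 became 1 without library 3 of 2 h, library 12 of 24 h or control library 31. Underground the 11 became 17 without library 2 of 2 h, 7 without any single control library and 30 with library weights.

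Genes next to each other in the deposited list changed alike. For neighbours whose identifiers share their first part, the log2 changes correlated across 14823 aboveground and 14310 underground pairs at r between 0.076 and 0.133 in the 8 comparisons. Each r was above all of 1000 permuted pairings, which reached at most 0.0332 (one-sided permutation p = 0.001, adjusted p = 0.001, the smallest they can give, with genes not independent replicates). Aboveground at 6 h, where 0 genes were called, r was still 0.0908, so these correlations need not concern the treatment. As a hypothesis, neighbouring genes may share part of their response, if the order of the list follows the genome. Reads shared between near-identical neighbouring copies could give the same values (highest r 0.133), and these cannot be told apart because no sequence was used here.

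A look at genes seen in few libraries led to a test of the title numbers. In all, 98 genes had at least 1 TPM in exactly 1 aboveground and 1 underground library and were at 0 in every other library. The libraries shared their number for 20 of these genes, against 8.28 when the numbers were shuffled within each time (one-sided permutation p = 0.005, 10000 shuffles). This is consistent with same-numbered libraries coming from the same plants, whose genes differ in presence, and sample handling shared by number was not tested against it. An earlier look at genes present in a single group only is not reported further.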
